A study of Mus musculus with 35 samples.

How the data were processed

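Total RNA (200 ng per mouse) from the colon of 35 mice had been hybridised to Affymetrix Mouse Gene 1.0 ST arrays. Per the labels, the authors normalized the signal with RMA in Affymetrix Expression Console 1.1, and the deposited values are log2 signal. Values ranged from 3.78 to 14.4, in keeping with that scale. Versions of further upstream tools are not given in the sources used here. All 35 arrays were used, and 0 value columns were left out. Of 28090 probe sets, 23178 were annotated and 4912 were not listed. Of the annotated probe sets 21639 had 1 gene symbol and 1539 had several, which were left out. Genes with more than 1 probe set (990) were represented by the one with the highest mean signal, leaving 19908 genes. Entrez numbers matched 21548 probe sets to a gene table of the GRCm38.p6 build, used for names and neighbouring genes only. Pair correlations of arrays ranged from 0.871 to 0.994.

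Groups followed titles and design text. The comparisons were 7 of 2 groups and 1 interaction. They were DSS against untreated within each genotype, transgenic against wild-type without and with DSS, transgenic against wild-type flora, each flora against axenic controls, and the difference between the DSS effects. Linear models with moderated variance were fitted in limma 3.58.1 (R 4.3.3) to the arrays of each comparison, two-sided, and adjusted by the Benjamini-Hochberg method over all genes. A gene was called at adjusted p under 0.05, and changes of at least 2-fold were also counted. SE stands for the moderated standard error and ± for the SD over mice. The groups of a gene did not overlap if all 5 mice of 1 group lay above all 5 of the other, which happens in 0.794% of genes by chance.

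Gene lists (41, with 821 genes, of which 738 were measured and 83 were not) were fixed before the data were examined. Lists with at least 5 measured genes, 39 in all, were tested with camera at a preset correlation of 0.01, with camera with an estimated correlation and with fry, each adjusted over the lists. Counts adjusted over the list alone used the genes of that list only. Each mouse also had a score per list, the mean over genes of its difference from the mean of the reference group, which was untreated wild-type for conventional mice and controls for axenic mice. Scores were compared by exact permutation over 252 assignments, two-sided, with a smallest possible p of 0.00794. Differences between 2 score effects permuted labels within each pair over 63504 assignments, which tests against no genotype or flora effect in either setting. Scores used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

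Named genes were the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, or the 5 with the smallest p in a direction where fewer than 5 passed. For each list up to 4 members with the smallest p were named, and a fixed set of colitis and Reg genes was always eligible. Gene names of predicted or unnamed type were skipped. Genes singled out as still called with the posterior Hox covariate were chosen after their values were seen. Samples were regrouped 100 times with a fixed seed for each comparison.

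Alternatives were array weights, all 35 arrays in 1 model, quantile normalization within each comparison, a variance model with trend and robust weights, a smooth muscle covariate, the mean of the probe sets of a gene, all probe sets, genes above the 40th percentile of mean signal, other list tests, other list scores and leaving out each mouse. Alternatives chosen after seeing the data were covariates of within-array SD, pancreas, Xist or posterior Hox level and leaving out the 7 arrays with the lowest within-array SD (1.76 or less). The calls were tested on simulated data with 200 changed genes among 19908. At 2-fold 68.7% of them were called for DSS in wild-type mice, 92.5% for DSS in transgenic mice, 76.1% for the interaction, 85.1% for genotype without DSS and 77.6% with DSS. For the donor effect it was 82.1%, for wild-type flora 91.0% and for transgenic flora 77.6%. At 1.5-fold the share ranged from 16.4% to 64.2% and at 4-fold from 95.5% to 98.5%, with 5 to 13 unchanged genes called. Noise was drawn for each gene on its own, without the shared movement of genes across the real arrays. These shares and false calls therefore need not hold for the real data. Labels give 1 strain and no batch, cage, sex or date, so none of these was modelled.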

Results

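Total RNA from the colon of 35 mice was measured on Affymetrix Mouse Gene 1.0 ST arrays, with 1 array per mouse and 5 mice in each of 7 groups. Conventional mice were wild-type or Reg3a-transgenic, and each genotype was either untreated or given 3% dextran sulfate sodium (DSS) in the drinking water for 5 days. DSS injures the colon epithelium and causes colitis. The other 3 groups were axenic (germ-free) mice given DSS. They were recipients of intestinal flora from wild-type donors, recipients of flora from transgenic donors, both transplanted 3 weeks before DSS, and controls whose label places DSS ahead of a microbial transfer. Whether and when these controls received flora is not given in the sources used here, so they need not have been free of flora. The protocol gives day 12 for the collection of colons and names no other day for the controls. A treatment characteristic also places the conventional mice after a microbial transfer, whereas the titles and the design text describe untreated or DSS-treated wild-type and transgenic mice. Titles and design text were followed. Median log2 signal per array ranged from 6.65 to 6.95, and the standard deviation over the probe sets of an array ranged from 1.64 to 2.03. That spread averaged 1.87 in untreated wild-type, 1.83 in untreated transgenic, 1.87 in DSS wild-type and 1.90 in DSS transgenic mice. In the axenic mice it averaged 1.96 with wild-type flora, 1.83 with transgenic flora and 1.73 in controls. Xist, a transcript of female cells, read 10.9 or more in 2 of 5 mice of each conventional group and 5.38 or less in every other mouse, including all axenic mice.

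**Figure D1:**
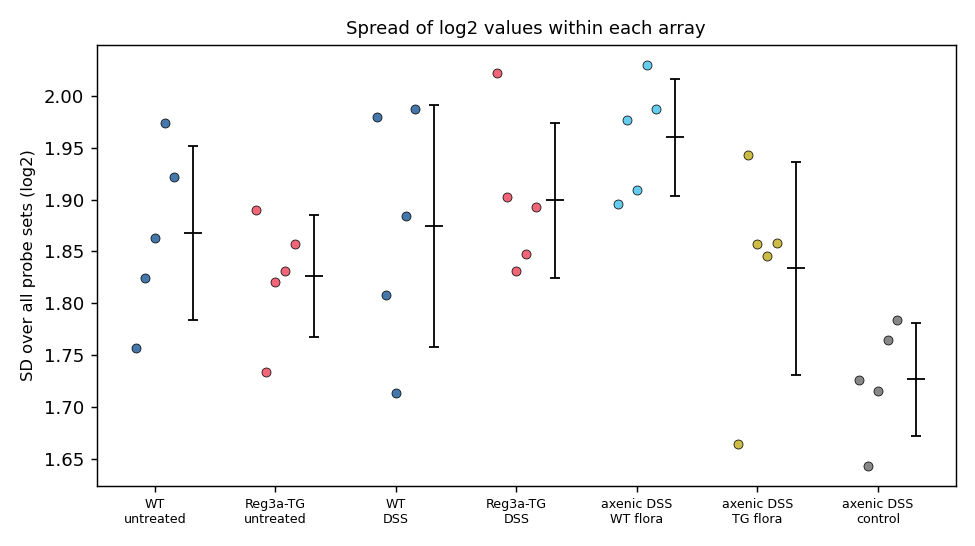
Standard deviation of log2 signal over all probe sets of each array, by group, with 1 point per mouse and a bar for the group mean and its SD. Arrays of wild-type-flora recipients averaged 1.96 and arrays of axenic controls averaged 1.73.

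Reg3a encodes a secreted lectin that binds gut bacteria, and the labels name it as the transgene. The mouse Reg3a probe set read 5.25 ± 0.20 (log2, SD, n = 5) in untreated wild-type and 5.15 ± 0.06 in untreated transgenic mice. Under DSS it read 5.20 ± 0.17 in wild-type and 5.05 ± 0.11 in transgenic mice. The genotypes differed by -0.10 without DSS (SE 0.10, adjusted p = 0.987) and by -0.15 with DSS (SE 0.10, adjusted p = 1.0). The species of the transgene and its promoter are not given in the sources used here, so this probe set need not read the transgene.

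What DSS colitis changed in wild-type mice was asked by comparing 5 DSS-treated with 5 untreated mice. Antimicrobial products of the epithelium had the 3 largest rises among the genes named. Retnlb, a bactericidal goblet-cell protein, rose from 5.14 ± 0.42 to 12.43 ± 0.28, a log2 change of 7.29 (SE 0.21, adjusted p = 1.51e-08). The lectins Reg3g and Reg3b rose by 6.59 (SE 0.34, adjusted p = 3.53e-06) and 5.92 (SE 0.54, adjusted p = 0.000357). Clca4b rose by 5.46, Plet1 by 5.39, Sptssb by 4.83, the acute phase gene Saa3 by 4.51, Il1b by 3.87, Dhrs9 by 3.72 and Lcn2 by 3.47 (adjusted p from 8.57e-08 for Plet1 to 0.00603 for Lcn2). Mptx1 fell by 5.95 (SE 0.32, adjusted p = 4.9e-06), Tgm3 fell by 4.14 (SE 0.80, adjusted p = 0.0151) and Cyp2f2 fell by 3.37 (SE 0.34, adjusted p = 0.000482). Further falls were in Slc37a2 (-3.31), Hoxb13 (-3.07), Slc15a1 (-2.98), Kyat1 (-2.97), Cyp2c68 (-2.69), Atp12a (-2.64) and Eno3 (-2.47). For each of these genes all 5 DSS mice lay on 1 side of all 5 untreated mice. In all, 1022 genes passed at adjusted p under 0.05, of which 425 were lower and the others higher, and 295 rose and 165 fell at least 2-fold. The higher share was 58.4%, and it went to 38.1% with the pancreas covariate, 49.5% with quantile normalization, 47% without untreated WT9 and 69.8% without DSS WT56. Over all genes 1227 (6.16%) did not overlap between the groups, where chance gives 0.794%.

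Inflammatory groups rose in DSS wild-type mice. Of 20 neutrophil genes 5 rose, with S100a8 at 3.23 and Clec4e at 2.06, and 12 rose adjusted over the list alone (camera adjusted p = 6.79e-08; adjusted p = 0.279 with an estimated correlation). Chemokines rose in 7 of 28 (13 adjusted over the list alone), among them Cxcl9 at 3.25, Ccl3 at 2.36 and Cxcl10 at 2.31 (camera adjusted p = 1.65e-07; adjusted p = 0.157 with an estimated correlation). Cytokines rose in 6 of 28 (6 adjusted over the list alone), led by Il1b and Ptgs2 (2.63) (camera adjusted p = 0.000468; adjusted p = 0.422 with an estimated correlation). Acute phase and complement genes rose in 7 of 18 (10 adjusted over the list alone), including Hp at 3.19 (camera adjusted p = 1.71e-09; adjusted p = 0.111 with an estimated correlation). Interferon-stimulated genes rose in 11 of 22 (17 adjusted over the list alone), including Zbp1 at 2.13 and Oas2 at 1.05 (camera adjusted p = 2.04e-16; adjusted p = 0.144 with an estimated correlation). Il6 (1.06, adjusted p = 0.316), Cxcl5 (1.59, adjusted p = 0.102), Ifng, Il17a and Cxcl1 did not pass. The inflammation score, a mean over the neutrophil, cytokine, chemokine and acute phase genes, was higher by 0.861 in DSS wild-type mice (exact permutation p = 0.00794, the smallest the design allows; adjusted p = 0.0278 over 7 comparisons; higher in 5 of 5 mice). Single DSS mice scored from 0.29 to 1.61.

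**Figure D2:**
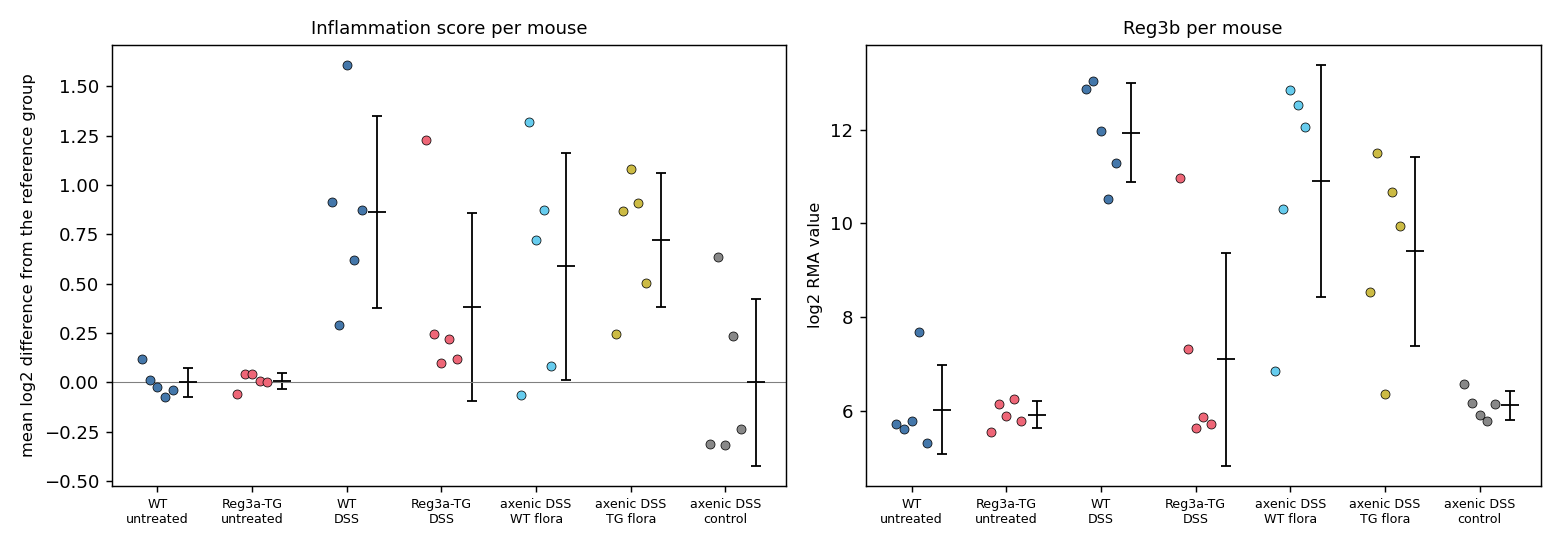
Inflammation score per mouse (left, mean log2 difference from the reference group) and log2 signal of Reg3b per mouse (right) in the 7 groups. Points are mice and bars are the mean and SD. DSS mouse TG49 scored 1.23 and the other 4 DSS transgenic mice scored 0.247 or less.

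Epithelial and stromal groups also moved with DSS in wild-type mice. Antimicrobial genes rose in 7 of 23 and fell in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 1.84e-08), the fall being Reg4 (-1.68, adjusted p = 0.0339). Genes of regenerating epithelium rose in 8 of 21 (8 adjusted over the list alone; camera adjusted p = 3.45e-06), with Sprr1a at 1.96, Ly6d at 1.34, Il33 at 1.23 and Phlda1 at 0.92. Crypt stem genes fell in 6 of 18 and rose in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 6.43e-05), with Lgr5 at -1.01, Ascl2 at -0.96, Znrf3 at -0.79 and Rnf43 at -0.78. Cell-cycle genes rose in 13 of 27 (24 adjusted over the list alone), with Ccna2 at 2.34, Plk1 at 1.88, Ccnb2 at 1.83 and Cdk1 at 1.76 (camera adjusted p = 8.75e-22; adjusted p = 0.157 with an estimated correlation). Collagens and matrix enzymes rose in 14 of 27 (21 adjusted over the list alone), with Timp1 at 2.82, Col1a1 at 1.36 and Col3a1 at 1.33 (camera adjusted p = 2.04e-16; adjusted p = 0.157 with an estimated correlation). Endoplasmic reticulum stress genes rose in 9 of 20 (10 adjusted over the list alone), with Pdia6 at 1.43, Hsp90b1 at 1.33 and Hspa5 at 1.22 (camera adjusted p = 4.53e-07; adjusted p = 0.157 with an estimated correlation). Absorptive colonocyte genes fell in 8 of 34 and rose in 2 (16 and 7 adjusted over the list alone), with Slc20a1 at -2.46, Trpm6 at -1.46, Aqp8 at -2.13 and Slc26a3 at -1.33 (camera adjusted p = 0.00169; adjusted p = 0.489 with an estimated correlation). Posterior Hox genes, which mark the position along the gut, fell in 5 of 8 (5 adjusted over the list alone; camera adjusted p = 2.96e-05), with Hoxd13 at -2.12, Hoxd11 at -1.29 and Hoxd12 at -0.52. Without DSS, Hoxd13 also read 6.228, 5.937 and 5.778 in transgenic mice TG631, TG31 and TG28, though 6.81 and 8.213 in TG26 and TG29. The position sampled was not tested, so it and DSS cannot be told apart for these genes. Clock genes fell in 10 of 15 and rose in 1 (11 and 2 adjusted over the list alone; camera adjusted p = 4.18e-10), with Ciart at -2.14, Per3 at -1.67, Per2 at -1.13 and Tef at -1.04. They were also lower in untreated transgenic than in untreated wild-type mice (Per2 by -1.12), so low clock genes were not particular to DSS.

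Of the 39 lists tested by camera, 29 passed in this comparison. The antimicrobial, regenerating, stem, clock and posterior Hox lists passed with an estimated correlation as well (adjusted p = 0.0249, 0.0347, 0.0267, 0.0267 and 0.0273), and no other did. With the mean level of the posterior Hox genes as a covariate, 9 genes passed instead of 1022, and among those named Retnlb, Plet1, Reg3g, Clca4b and Mptx1 were still called, while Hoxd11 and Hoxd13, themselves part of the covariate, turned to 0.30 and 0.21. The median SE over all genes grew from 0.15 to 0.278, while the median size of the change of the 1022 genes went from 0.93 to 0.783 and 982 of them kept their direction. Without DSS, Plet1 also read 11.14 and 11.3 in transgenic mice TG31 and TG28, and 7.072 to 8.967 in the other untreated transgenic mice. In untreated wild-type mice Plet1 read 6.998 to 7.904, so a high Plet1 was not particular to DSS. TG31 and TG28 also had the lowest Hoxb13 of their group (8.529 and 8.887), and the cause was not tested. With 1 mouse left out the count went to 424 (untreated WT7), 447 (untreated WT8), 489 (untreated WT10), 605 (untreated WT11), 556 (DSS WT65), 675 (DSS WT53) and 628 (DSS WT52).

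**Figure D3:**
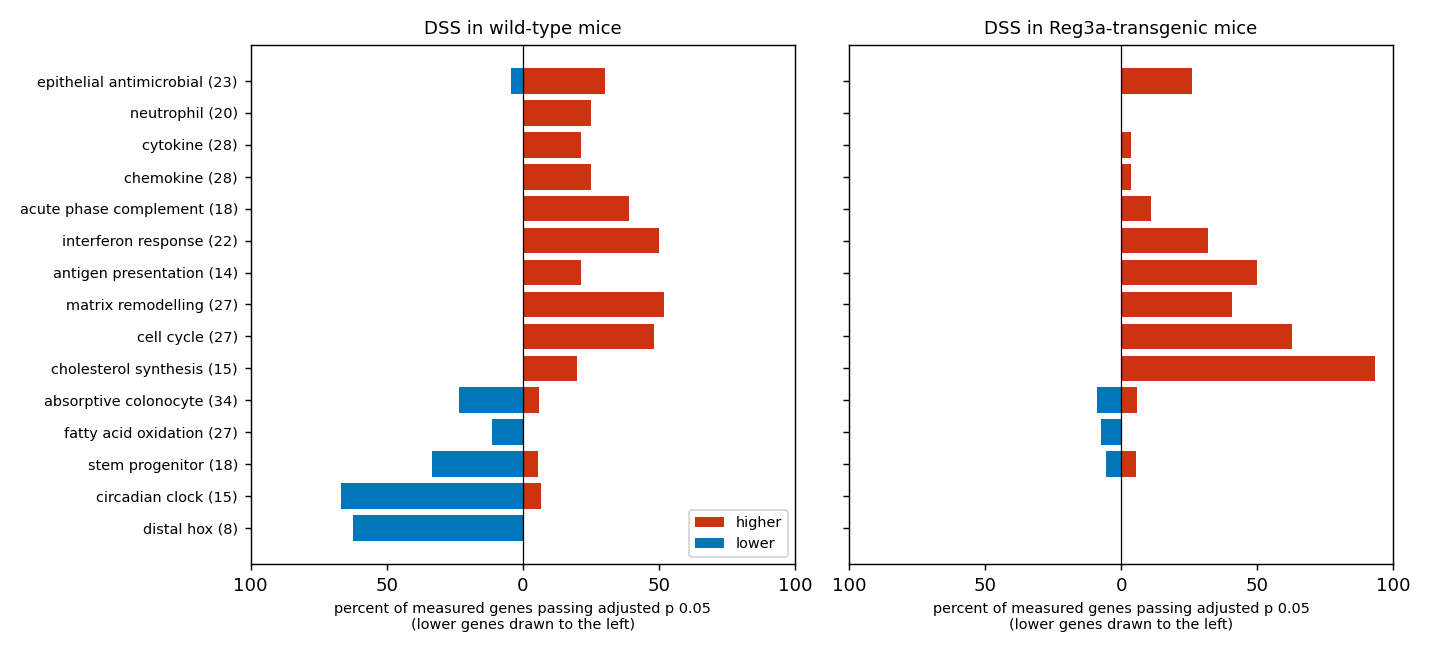
Percent of the measured genes of 15 gene lists that passed at adjusted p under 0.05 in the DSS comparison, higher to the right and lower to the left, for wild-type mice (1 panel) and transgenic mice (the other panel). In transgenic mice 14 of 15 cholesterol synthesis genes rose. The DSS effect on the score of that list differed by 0.219 between the genotypes (exact permutation p = 0.474).

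The same question was asked in Reg3a-transgenic mice. Clca4b rose by 4.69 (SE 0.44, adjusted p = 0.00299) and Retnlb by 4.19 (SE 0.69, adjusted p = 0.0122), from 5.59 ± 1.17 to 9.78 ± 1.41. Nos2 rose by 2.69, Nox1 by 2.39 (SE 0.25, adjusted p = 0.00344), Duoxa2 by 2.16 and Duox2 by 2.05. Dhrs9 rose by 2.52, Pla2g2a by 2.46, Cd177 by 2.24 and Ms4a12 by 2.08. Mptx1 fell by 3.47 (SE 0.695, adjusted p = 0.0225), and smaller falls were in Ces1d (-1.65), Vsig2 (-1.53), Pdk4 (-1.47), Ces2a (-1.32), Dpyd (-1.24), Mep1a (-1.19), B3galt2 (-1.19), Zfp600 (-1.19) and Apob (-1.19). All 5 DSS mice lay on 1 side of all 5 untreated mice for each of these genes. Reg3g (1.85, SE 0.93, adjusted p = 0.228), Reg3b (1.18, SE 0.86, adjusted p = 0.38), S100a8 (0.96, adjusted p = 0.361), Il1b (1.89, adjusted p = 0.111) and Lcn2 (1.63, adjusted p = 0.139) did not pass. In all, 689 genes were higher and 216 lower, of which 148 and 15 changed at least 2-fold. Over all genes 1732 (8.7%) did not overlap between the groups, against 0.794% by chance.

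Sterol synthesis genes rose in 14 of 15 in transgenic mice (14 adjusted over the list alone), with Idi1 at 1.34, Nsdhl at 1.04, Hmgcs1 at 0.97 and Mvk at 0.65 (camera adjusted p = 1.58e-14; adjusted p = 0.294 with an estimated correlation). Cell-cycle genes rose in 17 of 27 (23 adjusted over the list alone), with Top2a at 1.54, Ccnb2 at 1.33, Cdk1 at 1.31 and Aurkb at 1.14 (camera adjusted p = 3.57e-18; adjusted p = 0.298 with an estimated correlation). Matrix genes rose in 11 of 27 (20 adjusted over the list alone), including Col1a1 at 1.25 and Sparc at 1.23 (camera adjusted p = 2.73e-13; adjusted p = 0.298 with an estimated correlation). Antigen presentation genes rose in 7 of 14 (9 adjusted over the list alone), with H2-Ab1 at 1.64 and Cd74 at 1.51 (camera adjusted p = 3.78e-07, adjusted p = 0.391 with an estimated correlation). Sterol synthesis scores were -0.141 to 1.12 in DSS wild-type and 0.7 to 1.11 in DSS transgenic mice. Antigen presentation scores were 0.0737 to 1.43 and 0.773 to 1.64. The DSS effects of the genotypes differed by 0.219 (exact permutation p = 0.474) and -0.0537 (exact permutation p = 0.877) in these scores. Neither rise was thus shown to be particular to transgenic mice. Interferon-stimulated genes rose in 7 of 22 (15 adjusted over the list alone), with Rtp4 at 1.46, Ifit1 at 1.37 and Usp18 at 1.13 (camera adjusted p = 3.13e-09; adjusted p = 0.391 with an estimated correlation). Antimicrobial genes rose in 6 of 23 (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00155; adjusted p = 0.298 with an estimated correlation). None of the 20 neutrophil genes passed in limma (camera adjusted p = 0.0488; adjusted p = 0.586 with an estimated correlation), nor did any clock or posterior Hox gene (camera adjusted p = 0.958 and 0.649). The clock list had a median of -0.01 while camera pointed up. Camera passed 26 lists, and 0 passed with an estimated correlation, where fry passed 9. The inflammation score was higher by 0.376 (exact permutation p = 0.00794, adjusted p = 0.0278, higher in 5 of 5 mice), and by 0.165 without DSS mouse TG49. With a median over genes it was 0.186 (exact permutation p = 0.0794) and with scaled genes 0.291 (exact permutation p = 0.135), past the threshold in neither. The difference lost its call without untreated mouse TG631 (0.36, exact permutation p = 0.0635). With the smooth muscle list as a covariate 47 genes passed, with the spread covariate 350 (284 of them among the 905), with the pancreas covariate 223, with all 35 arrays in 1 model 600 and with array weights 3266. The higher share was 76.1% and went to 57.3% with array weights. The gene count went to 178 without DSS TG48, 420 without DSS TG46, 549 without DSS TG44, 1668 without DSS TG47, 230 without untreated TG26, 283 without untreated TG29, 587 without untreated TG31 and 596 without untreated TG631.

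Whether the DSS response differed by genotype was tested as an interaction over the 4 conventional groups. Clock genes were among the 31 genes that passed, 30 of which moved up in transgenic relative to wild-type mice. Dbp differed by 2.20 (SE 0.37, adjusted p = 0.0228), Ciart by 2.03, Per3 by 1.65, Per2 by 1.19 (SE 0.13, adjusted p = 0.000646) and Tef by 0.96, so 5 of 15 clock genes passed (11 up and 1 down adjusted over the list alone). Untreated wild-type mice stood apart here, as a mean of 10 clock genes read 8.55 in them and 7.187 to 7.594 in the other groups. Between genotypes Per2 differed by -1.12 without DSS and by 0.067 with DSS. Kyat1 differed by 2.35 (SE 0.38, adjusted p = 0.0227), Unc119 by 1.96, Gsta3 by 1.93, Cbr2 by 1.84, Trpv3 by 1.81, Wfdc2 by 1.66 and Smim24 by 1.60. The glutathione transferases Gstm1 (1.34) and Gstm3 (1.28) passed among 36 xenobiotic and bile acid genes (2 adjusted over the list alone; camera adjusted p = 0.0335; adjusted p = 0.61 with an estimated correlation). The chaperone Hsph1 differed by -0.99 (SE 0.17, adjusted p = 0.0293) and was the only gene moving down here, although 82.2% of 45 genes moved up without DSS mouse TG49 and 73.3% of 232 with array weights. The next smallest p downward were those of Hsd17b13 (-1.10, adjusted p = 0.0645), DQ267102 (-0.97, adjusted p = 0.0931), Hspa5 (-1.01, adjusted p = 0.0992) and Reg3g (-4.74, SE 1.08, adjusted p = 0.0992), none of which passed. Reg3b (-4.74, adjusted p = 0.105) did not pass either, so the difference between the lectin responses was not established. At least 2-fold differences were seen in 21 genes upward and 0 downward, and 1478 genes had an unadjusted p under 0.05 in limma.

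Clock and stem genes moved up as groups in the interaction by camera (adjusted p = 2.63e-14 and 0.000277) and with an estimated correlation (adjusted p = 0.000739 and 0.0085). No stem gene passed over all genes, where 6 of 18 did adjusted over the list alone. Posterior Hox genes moved up (camera adjusted p = 0.00037; adjusted p = 0.0621 with an estimated correlation) and neutrophil genes down (camera adjusted p = 0.000668; adjusted p = 0.61 with an estimated correlation), with 0 of their genes passing over all genes and 1 and 0 adjusted over the list alone. With the posterior Hox level as a covariate no gene passed in limma, as the median SE grew from 0.193 to 0.239 and the median size of the 31 differences fell from 1.31 to 0.802, all in the same direction. With the smooth muscle covariate 16 passed. Among untreated mice, leaving out 1 gave 4 genes for WT8, 7 for WT7, 9 for WT10, 13 for WT11, 59 for WT9, 15 for TG631, 4 for TG31 and 10 for TG28. Among DSS mice it gave 14 for WT56, 5 for TG48, 5 for TG47, 10 for TG46 and 10 for TG44. The inflammation score gave an interaction of -0.485 (exact permutation p = 0.142).

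How alike the DSS responses of the genotypes were was described across genes, which are not independent replicates. Across all genes the change in transgenic mice correlated with that in wild-type mice at r = 0.656 (jackknife SE over mice 0.235) with a slope of 0.501. Of the 1022 genes called in wild-type mice, 943 (92.3%) changed in the same direction in transgenic mice, 274 were called in both, and 972 (95.1%) changed less in transgenic mice, with a median ratio of 0.481. These genes were picked for their change in wild-type mice, which on its own makes the other change smaller.

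Without DSS, the transgene comparison set 5 transgenic against 5 wild-type mice. Nxpe5, of a family of neurexophilin-like proteins, was higher by 3.87 in transgenic mice (9.76 ± 0.73 against 5.89 ± 0.17, SE 0.29, adjusted p = 0.00038). Hsd17b13, a lipid droplet enzyme, was higher by 1.79 (SE 0.16, adjusted p = 0.000681), and Cox18 (0.78), Entpd4 (0.74) and Afm (0.71) were higher. Nnt, a mitochondrial transhydrogenase, was lower by a log2 change of -1.28 (7.37 ± 0.13 against 8.65 ± 0.18, SE 0.10, adjusted p = 0.000477). The clock genes Dbp (-1.84, SE 0.28, adjusted p = 0.0469), Per2 (-1.12, SE 0.10, adjusted p = 0.000575) and Tef (-0.92) were lower, as were Kyat1 (-1.58), Usp2 (-1.23), Rdh18-ps (-1.08), Zfyve21 (-0.85), Camk2b (-0.72) and Klc1 (-0.55). These 15 genes were all that passed. Over all genes 222 (1.12%) did not overlap between the genotypes, where chance gives 0.794%. No named antimicrobial or inflammatory gene passed: Reg3b differed by -0.11, Reg3g by 0.34, S100a8 by 0.05 and Il1b by 0.24.

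Clock genes fell as a group without DSS, 3 of 15 over all genes and 10 (with 1 rising) adjusted over the list alone (camera adjusted p = 1.21e-13, adjusted p = 0.0214 with an estimated correlation). This was the only one of 17 lists passed by camera that held with an estimated correlation. Its per-mouse score was lower by a difference of -0.633 (exact permutation p = 0.00794, lower in 5 of 5 mice). No list score passed after adjustment over 39 lists, but only 2 had an unadjusted exact permutation p under 0.05. So few lists cannot pass at the smallest p the design allows, so this failure says nothing about the clock score. The inflammation score differed by 0.00663 (exact permutation p = 0.881). Leaving out 1 mouse gave 4 genes for WT8, 4 for WT7, 5 for WT11, 5 for WT10, 4 for TG631, 5 for TG31, 8 for TG29 and 4 for TG28.

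**Figure D4:**
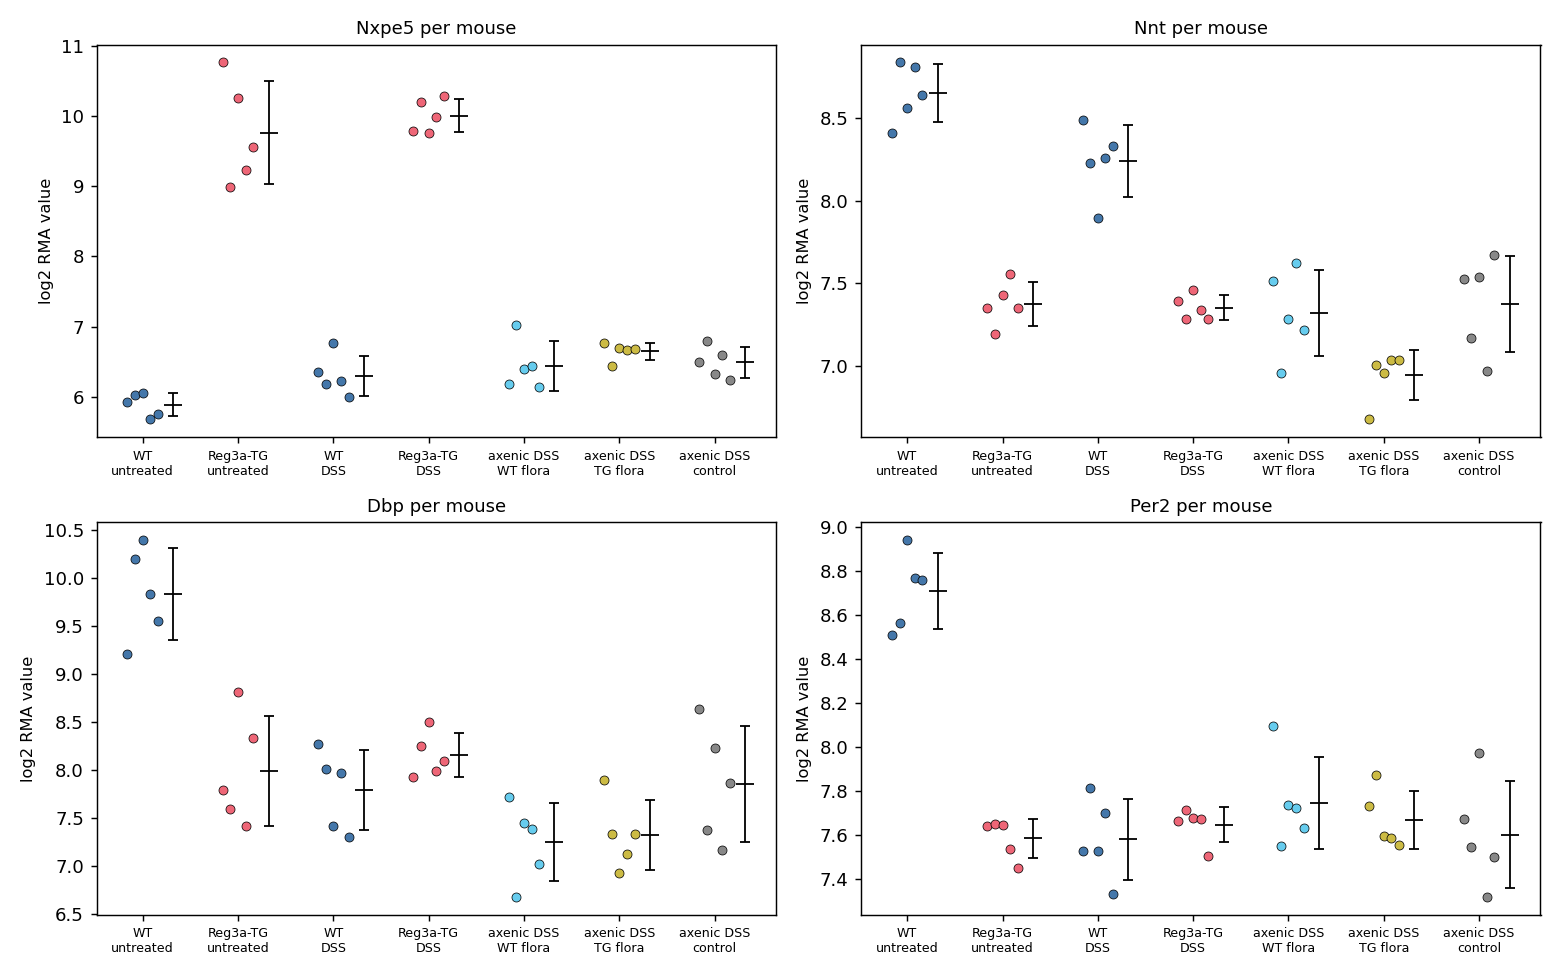
Log2 signal of Nxpe5, Nnt, Dbp and Per2 per mouse in the 7 groups, with the mean and SD of each group. Untreated transgenic mice averaged 9.76 for Nxpe5 and untreated wild-type mice 5.89.

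With DSS, the transgene comparison called 1 gene. Nxpe5 was higher by 3.70 in transgenic mice (against 6.30 ± 0.29 in wild-type mice, SE 0.16, adjusted p = 2e-06), with all 5 mice above all 5. The next smallest p upward were those of Slc39a5 (0.61, adjusted p = 0.0842), Ephb3 (0.69, adjusted p = 0.0842), Emp2 (0.90, adjusted p = 0.0885) and Fbxo36 (0.76, adjusted p = 0.0885), and none passed. Downward they were those of Nnt (-0.89, adjusted p = 0.0622), Hsph1 (-0.91, adjusted p = 0.0987), Camk2b (-0.81, adjusted p = 0.13), Hspa5 (-0.73, adjusted p = 0.186) and Reg3b (-4.84, SE 0.96, adjusted p = 0.227). Reg3g differed by -4.40 (SE 0.97, adjusted p = 0.29), Retnlb by -2.65 (adjusted p = 0.261), Lcn2 by -2.44 (adjusted p = 0.621), S100a8 by -2.21 (adjusted p = 0.941) and Reg4 by 1.93 (adjusted p = 0.31), and none passed. At an unadjusted p under 0.05 limma gave 1030 genes, and 313 (1.57%) did not overlap against 0.794% by chance. Array weights called 339 genes, the within-array SD covariate 69, all 35 arrays in 1 model 36 and the pancreas covariate 16.

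Crypt stem genes were higher in transgenic mice under DSS as a group, 0 of 18 over all genes and 7 adjusted over the list alone, with Lgr5 at 0.75 (adjusted p = 0.238) and Ephb3 at 0.69 (camera adjusted p = 6.03e-08, adjusted p = 0.0106 with an estimated correlation). This was the only list of the 26 passed by camera that held with an estimated correlation. Acute phase genes (0 lower over all genes, 4 adjusted over the list alone; camera adjusted p = 1.33e-09; adjusted p = 0.13 with an estimated correlation), neutrophil genes (0 and 0; camera adjusted p = 4.07e-06; adjusted p = 0.425 with an estimated correlation) and antimicrobial genes (0 over all genes, 3 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000476; adjusted p = 0.13 with an estimated correlation) were lower as groups. Posterior Hox genes were higher as a group (camera adjusted p = 0.00425, adjusted p = 0.13 with an estimated correlation). Hoxb13 differed by 2.19 without passing in limma (adjusted p = 0.359). It read 9.716 to 10.29 in transgenic and 6.395 to 9.646 in wild-type mice under DSS. The position sampled was not tested, so it and genotype cannot be told apart for these genes. Whether position also bears on the other differences under DSS was not tested. The inflammation score was lower by a difference of -0.478 (exact permutation p = 0.135), at -0.69 without TG49 (exact permutation p = 0.0159) and at -0.292 without WT55 (exact permutation p = 0.294). The gene count went to 2 without WT65, 11 without WT55 and 4 without TG49.

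Whether flora of transgenic donors acted differently from flora of wild-type donors was tested in axenic recipients given DSS. No gene passed in limma, with 6856 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0695. Array weights called 4886 genes and all 35 arrays in 1 model 1927. Over all genes 1480 (7.43%) did not overlap between the donors, against 0.794% by chance. Genes with the smallest p upward in transgenic-flora recipients were Mmp12 (0.64), Cyp3a25 (0.62), Csta3 (0.64), Prl7c1 (0.90) and Taar9 (0.66). Downward they were Ifi35 (-0.65), Atp5e (-0.61), Snrpb (-0.80), Psmb4 (-0.74) and Gadd45g (-0.92), each at that adjusted p. Reg3g differed by -2.23 (SE 1.30, adjusted p = 0.22) and Reg3b by -1.51 (SE 1.20, adjusted p = 0.35). Without recipient TG749 limma called 4700 genes and without recipient WT793 it called 149. Within-array spread averaged 1.83 in transgenic-flora and 1.96 in wild-type-flora recipients. Across genes, which are not independent replicates, the donor change correlated at r = -0.791 with the slope of each gene on spread in the conventional mice, a value computed after the data were seen.

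Respiratory chain genes were lower as a group in transgenic-flora recipients, 0 of 30 over all genes and 24 adjusted over the list alone, with Ndufa4 at -0.97, Ndufa1 at -0.90, Ndufv1 at -0.68 and Atp5o at -0.53 (camera adjusted p = 4.07e-09; adjusted p = 0.589 with an estimated correlation; adjusted p = 0.000575 with the spread covariate). Cell-cycle genes (14 of 27 adjusted over the list alone; camera adjusted p = 1.09e-06), fatty acid oxidation genes (19 of 27; camera adjusted p = 1.12e-05), smooth muscle genes (11 of 16; camera adjusted p = 2.79e-05) and sterol synthesis genes (8 of 15; camera adjusted p = 8.72e-05) were lower as groups with 0 passing over all genes (each at adjusted p = 0.589 with an estimated correlation). Neutrophil genes were higher as a group with 0 of 20 passing either way (camera adjusted p = 0.0441; adjusted p = 0.682 with an estimated correlation). The inflammation score differed by 0.134 (exact permutation p = 0.667), and no list score passed after adjustment, with 14 of 39 at an unadjusted exact p under 0.05. Exocrine pancreas genes had a median difference of -2.11 (camera adjusted p = 0.00623; adjusted p = 0.589 with an estimated correlation) and moved with Reg1 (-1.90), Reg2 (-2.25) and Reg3a (-2.09), none of which passed.

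Whether the genotype difference under DSS was seen again in flora recipients was asked across genes, which are not independent replicates. The changes correlated at r = -0.245, and 63 of 100 draws of permuted labels gave an r at least as high (highest other draw 0.809, lowest -0.847). Its direction turned without DSS mouse WT55 (r = 0.171) and without DSS mouse TG49 (r = 0.000989), and it was -0.456 without WT52, -0.415 without WT65, -0.391 without TG47, -0.12 without WT56 and -0.145 without recipient WT880. The 100 genes with the smallest p among those higher in transgenic mice under DSS had a mean change of -0.238 in recipients of transgenic flora (camera p = 1.56e-05 downward; p = 0.304 with an estimated correlation; fry p = 0.0638). For the 100 genes lower in transgenic mice the mean was -0.131 (camera p = 0.174 and fry p = 0.448 by rotation in limma, p = 0.729 with an estimated correlation). The inflammation score difference in axenic recipients exceeded that in conventional mice by 0.613 (exact permutation p = 0.164).

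What wild-type flora changed was asked against axenic controls. Retnlb rose by 5.95 (SE 0.41, adjusted p = 2.49e-05), from 5.53 ± 0.42 to 11.47 ± 0.99, and Plet1 by 5.51 (SE 0.16, adjusted p = 1.59e-08). Reg3g rose by 5.42 (SE 0.85, adjusted p = 0.000658) and Reg3b by 4.80 (SE 0.94, adjusted p = 0.00166). Clca4b rose by 4.72, Jchain, which joins secreted IgA, by 3.98, Sptssb by 3.77, Nos2 by 3.33, Duox2 by 3.30 and Cxcl9 by 3.29. Falls were smaller: Retn (-2.03), Ifnz (-1.72), Usp17ld (-1.60), Plb1 (-1.55), Sfi1 (-1.54), Fxyd4 (-1.53), Krtap5-2 (-1.52), Gpr31b (-1.47), Nr1d1 (-1.36) and Retnla (-1.32). All 5 recipients lay on 1 side of all 5 controls for each of these genes. Reg3a rose by 3.41 (SE 0.75, adjusted p = 0.0029), Reg2 by 5.10 and Reg1 by 3.15. These moved with the pancreas genes, 10 of 10 of which rose (10 adjusted over the list alone; median 3.26), among them Ctrb1 at 4.22 and Pnliprp1 at 3.57 (camera adjusted p = 0.00279; adjusted p = 0.556 with an estimated correlation). Recipient WT880 read 5.1 for Reg3a, 4.91 for Reg2 and 6.19 for Reg1, whereas the other 4 read at least 9.3, 10.5 and 10.3. In all, 6399 genes were higher and 7002 lower, of which 991 and 224 changed at least 2-fold. Over all genes 8896 (44.7%) did not overlap, against 0.794% by chance.

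Sterol synthesis genes rose in 15 of 15 (15 adjusted over the list alone), with Lss at 1.90, Nsdhl at 1.65 and Fdps at 1.24 (camera adjusted p = 1.5e-08; adjusted p = 0.385 with an estimated correlation). Interferon-stimulated genes rose in 16 of 22 (16 adjusted over the list alone), with Zbp1 at 1.72, Ifit2 at 1.70 and Irf1 at 1.70 (camera adjusted p = 3.37e-05; adjusted p = 0.385 with an estimated correlation). Antimicrobial genes rose in 12 of 23 and fell in 2 (12 and 2 adjusted over the list alone; camera adjusted p = 0.00147; adjusted p = 0.385 with an estimated correlation), B and plasma cell genes rose in 11 of 17 (11 adjusted over the list alone; camera adjusted p = 0.00279; adjusted p = 0.556 with an estimated correlation) and respiratory chain genes rose in 26 of 30 (26 adjusted over the list alone; camera adjusted p = 1.53e-06; adjusted p = 0.556 with an estimated correlation). Neutrophil genes rose in 6 of 20 and fell in 3 (2 and 2 adjusted over the list alone; camera adjusted p = 0.231), and the inflammation score rose by 0.587 (exact permutation p = 0.0952), at 0.75 without recipient WT880 and 0.746 without control CT517 (exact permutation p = 0.0476 for each). Of 23 lists passed by camera, 0 held with an estimated correlation, where fry passed 23. Arrays of these recipients had a spread of 1.96 against 1.73 in controls. With spread as a covariate 1 gene passed instead of 13401, Plet1 (5.51, SE 0.43, adjusted p = 0.00364). Retnlb was at 6.19 (SE 1.11, adjusted p = 0.829), Reg3g at 2.86 (SE 2.17, adjusted p = 1.0) and Reg3b at 2.09 (SE 2.39, adjusted p = 1.0), and Ifnz, Usp17ld and Gpr31b turned to 0.08, 0.02 and 0.36. Clca4b (4.90, SE 1.83), Jchain (4.11, SE 0.66) and Nos2 (3.78, SE 0.78) kept their size without being called. Sptssb, Duox2 and Cxcl9 went to 2.78, 2.465 and 2.33. The median SE over all genes grew from 0.117 to 0.246, and the median size of the change of the called genes fell from 0.519 to 0.158. Quantile normalization within the comparison called 6637 genes, 5074 of them among the 13401. Dropping the 7 arrays with the lowest spread left 5159 genes. Only CT229 and CT093 then remained as controls, so a smaller group and spread cannot be told apart there. The pancreas covariate left 1444 genes, with Reg1 at -0.04. The higher share went from 47.8% to 58.6% without the low-spread arrays, to 81.6% with the pancreas covariate and to 74.6% among genes above the 40th percentile of mean signal.

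Transgenic flora was compared with the same controls. Retnlb rose by 5.00 (SE 0.45, adjusted p = 0.000636), Plet1 by 4.77 (SE 0.35, adjusted p = 0.00013) and Clca4b by 4.73. Jchain rose by 4.29 (SE 0.25, adjusted p = 3.4e-05), and the immunoglobulin light chain genes Igkv9-120 and Igkv10-96 by 4.26 (SE 0.36, adjusted p = 0.000363) and 3.43. Neutrophil products rose, with S100a8 at 4.05 (SE 0.60, adjusted p = 0.0162), Mmp8 at 3.95 and Ngp at 2.99, and so did Lcn2 at 3.89 (SE 0.49, adjusted p = 0.00579) and Retnlg at 3.59. The hormone gene Nmu (-1.04, SE 0.13, adjusted p = 0.00671) and Retnla (-1.07, SE 0.16, adjusted p = 0.0183) fell. Next downward by p were Mylk (-0.73, adjusted p = 0.0557), Pcp4 (-0.66) and Gsdmc2 (-1.55), which did not pass. Reg3b (3.29, adjusted p = 0.1), Reg3g (3.19, adjusted p = 0.155) and Reg3a (1.33, adjusted p = 0.265) did not pass. In all, 65 genes were higher and 2 lower, 52 and 2 of them at least 2-fold. Over all genes 548 (2.75%) did not overlap between the groups, where chance gives 0.794%.

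Antimicrobial genes rose in 6 of 23 with transgenic flora (8 adjusted over the list alone), including Pla2g2a at 2.96, Nos2 at 2.83 and Duoxa2 at 2.35 (camera adjusted p = 7.99e-08, adjusted p = 0.0427 with an estimated correlation). No other of the 26 lists passed by camera held with an estimated correlation. Neutrophil genes rose in 3 of 20 (12 adjusted over the list alone; camera adjusted p = 1.58e-08; adjusted p = 0.382 with an estimated correlation) and B and plasma cell genes, including Pou2af1 at 1.37, in 2 of 17 (10 adjusted over the list alone; camera adjusted p = 4.82e-10; adjusted p = 0.382 with an estimated correlation). Sterol synthesis genes were higher as a group with 0 of 15 passing over all genes and 11 adjusted over the list alone (camera adjusted p = 2.36e-10; adjusted p = 0.382 with an estimated correlation). Smooth muscle genes were lower as a group with 0 of 16 passing and 6 adjusted over the list alone (camera adjusted p = 1.2e-06; adjusted p = 0.382 with an estimated correlation). The inflammation score was higher by 0.721 (exact permutation p = 0.0317, adjusted p = 0.0741, higher in 5 of 5 mice than the control mean). Without recipient TG749, TG713 or TG632 the raw exact permutation p was 0.0556, at 0.684, 0.632 and 0.674. The change with transgenic flora correlated across genes at r = 0.613 with the slope on spread in the conventional mice. With the spread covariate 65 genes passed, 28 of them among the 67, and the higher share went from 97.0% to 46.2%. Recipient TG922 had a within-array spread of 1.66, the lowest of its group, and without it 5307 genes passed, of which 49.8% were higher. The count went to 29 without TG749, 28 without TG632, 29 without TG446, 35 without control CT677, 27 without CT465 and 37 without CT093. The smooth muscle covariate gave 7113 genes, 43.7% of them higher, and array weights 6655, 47.6% of them higher.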

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

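The tests of the slope of spread, of the clock phase and of the drop without DSS, and both tests of the genotype genes, were chosen only after the result was seen. Single mice were singled out where their gap to the nearest mouse of their group, over the range of the group, passed Dixon's critical value at 95%. Chance singles out about 1 in 20 groups, so 23.4 were to be expected among the 469 groups of values tested, and 64 were found.

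DSS transgenic mouse TG49 stood above the other 4 mice of its group in 17 values. Its list scores were 1.48 for neutrophil, 1.15 for monocyte and macrophage, 0.46 for T and NK cell, 0.961 for cytokine, 1.29 for chemokine, 1.57 for interferon, 1.64 for antigen presentation, 1.46 for matrix genes and 1.23 for the inflammation score. Its log2 signal was 9.57 for S100a8, 9.5 for S100a9, 11.3 for Lcn2, 6.89 for Il6, 8.2 for Tnf, 7.78 for Ifng, 9.33 for Cxcl2 and 7.55 for Cxcl5. DSS wild-type mouse WT55 stood apart in 9 values. Its scores were -1.25 for absorptive colonocyte, -0.292 for goblet cell, -1.01 for fatty acid oxidation, -1.01 for clock and -0.284 for pancreas genes, and its log2 signal was 7.67 for Reg2, 7.63 for Il6, 8.64 for Cxcl1 and 9.98 for Slc26a3. DSS wild-type mouse WT56 read 7.46 for Nos2, below the others.

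Among untreated mice, wild-type mouse WT11 stood above its group with scores of 0.129 for monocyte and macrophage and 0.27 for interferon genes, and with Reg3b at 7.68 and Reg2 at 9.88. It stood below its group for Il6 at 4.24 (others 4.31 to 4.33) and Car1 at 13.1 (others 13.5 to 13.6). Wild-type mouse WT10 read 8.61 for Lcn2, WT9 read 6.39 for Tnf and WT7 scored 0.0901 for matrix genes. Transgenic mouse TG631 scored 2.29 for pancreas genes and read 10.5 for Reg1, TG28 scored 0.646 for interferon genes and TG31 scored -0.41 for hypoxia and glycolysis genes.

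Among axenic mice, transgenic-flora recipient TG922 stood apart with scores of 0.105 for monocyte and macrophage, -0.142 for sterol synthesis, -0.135 for hypoxia and glycolysis and 0.096 for anterior Hox genes, and with Nos2 at 8.73 and Mki67 at 8.62. Wild-type-flora recipient WT880 scored 1.08 for antimicrobial and -0.245 for pancreas genes and read 5.1 for Reg3a, 6.19 for Reg1 and 4.91 for Reg2. Wild-type-flora recipient WT793 scored 0.698 for T and NK cell, 0.319 for absorptive colonocyte and 0.138 for xenobiotic and bile acid genes and read 13.4 for Muc2. Control CT517 scored -0.491 for smooth muscle genes and read 7.96 for Il6, 8.02 for Tnf and 8.6 for Cxcl1. Control CT465 scored 1.28 for pancreas genes and read 5.63 for Reg2, both above the others. Control CT093 read 6.28 for Ifng, below the others (6.45 to 6.52). Transgenic-flora recipient TG713 read 12.4 for Car4 and 5.77 for Lgr5, both below the others.

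Differences between 2 effects were singled out next. The DSS effect differed by genotype in 31 genes by the interaction in limma. For list scores the permutation tests against no genotype or flora effect in either setting, so a small p does not by itself show that 2 effects differ. The difference between the DSS effects was 0.816 for clock genes (exact permutation p = 3.15e-05, adjusted p = 0.00123 over 39 lists), 1.02 for posterior Hox genes (exact permutation p = 0.00359, adjusted p = 0.0467) and -0.231 for small intestine and Paneth genes (exact permutation p = 0.00154, adjusted p = 0.03). The donor effect in axenic recipients minus the genotype effect under DSS was singled out in 8 lists. It was 0.332 for mast cell (adjusted p = 0.00491 by exact permutation), -0.472 for stem (adjusted p = 0.00491), -0.701 for tight junction (adjusted p = 0.0143) and -0.266 for clock genes (adjusted p = 0.016). It was -0.758 for absorptive colonocyte (adjusted p = 0.0339 by exact permutation), -0.613 for fatty acid oxidation (adjusted p = 0.0379), -0.747 for smooth muscle (adjusted p = 0.0449) and 0.24 for small intestine and Paneth genes (adjusted p = 0.0449).

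Counts of called genes were set against 100 splits of the same mice, the real one included. Few splits called at least as many genes as the real one for DSS in wild-type mice (1022 genes, 2 splits as large, highest other 4624), DSS in transgenic mice (905 genes, 1 split, highest other 535) and the interaction (31 genes, 3 splits, highest other 10750). The same held for genotype without DSS (15 genes, 3 splits, highest other 5365) and with DSS (1 gene, 3 splits, highest other 6234). It also held for wild-type flora (13401 genes, 1 split, highest other 5143) and transgenic flora (67 genes, 4 splits, highest other 7317) against controls. Only for DSS in transgenic mice and for wild-type flora did no other split reach the real count. For genotype with DSS the test asked only whether a split called any gene. These shares were not adjusted over the comparisons, so chance was not excluded. For the donor effect the real count was 0, so all 100 splits reached it by construction and the test says nothing about chance (highest other 6). Some splits called several times the real count for DSS in wild-type mice, the interaction, both genotype comparisons and transgenic flora, which points to a structure of these samples other than the groups.

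Wild-type-flora recipients differed from axenic controls in 13401 genes, and their arrays also differed in within-array spread. The change correlated across genes at r = 0.824 with the slope of each gene on spread in the conventional arrays, where no recipients entered, although genes are not independent replicates. After the change that spread predicts was subtracted, 17.3% of the 991 rises of at least 2-fold stayed at that size, although the 10 named rises stayed at 2.23 or more on the log2 scale. Spread is the SD of the same log2 values, so groups that differ in it tend to give such a correlation. Neither value can tell spread as a cause of these rises from spread as a result of them. A difference in array spread thus stays open as a cause of most of these rises. With controls divided so that none stood on both sides, the change that spread predicts was first subtracted on each side. A median of 150.5 called genes then rose at least 2-fold with wild-type flora. A median of 71.1% of them (38.4% to 86.4% over 10 divisions) were also at least 1.5-fold higher in transgenic-flora recipients, against 2.75% of all genes. An effect of flora of either donor thus stays open too. Arrays of transgenic-flora recipients also had a higher spread than those of controls (1.83 against 1.73), subtracted here only with slopes from the conventional arrays. The labels leave open whether the controls were free of flora. Quantile normalization within the comparison, which gives its arrays the same distribution of gene values, still called 6637 genes, 5074 of them among the 13401. An unequal distribution as such thus did not carry those calls, but gene changes that go with spread may remain in them. Flora and spread were therefore not separated, except that spread alone was argued against for Plet1 (5.51 before and with the covariate, adjusted p = 0.00364). Retnlb, Jchain, Clca4b and Nos2 went from 5.95, 3.98, 4.72 and 3.33 to 6.19, 4.11, 4.90 and 3.78 with the covariate. With SE of 0.66 to 1.83 none of them was called. The other named rises, Reg3g, Reg3b, Sptssb, Duox2 and Cxcl9, shrank to 2.86, 2.09, 2.78, 2.465 and 2.33.

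Clock genes were lower in untreated transgenic and in DSS wild-type mice than in untreated wild-type mice, with a mean of the Dbp and Per group of 8.55 (SD 0.215) in untreated wild-type, 7.594 in untreated transgenic, 7.319 in DSS wild-type and 7.582 in DSS transgenic mice and 7.187 to 7.373 in the axenic groups. DSS as the only cause was argued against, since 77.7% of it was present without DSS, and so was array spread, since 94.7% of the mean change was kept with the spread covariate. Taken alone, 4 genes of the opposite phase averaged 0.236 higher in untreated transgenic than in untreated wild-type mice (exact permutation p = 0.0476, 4 of 5 mice above the wild-type mean), and none passed in limma. Arntl carried most of this at 0.674 (adjusted p = 0.678), with Nfil3 at 0.193, Clock at 0.108 and Cry1 at -0.0311. A different time of day or clock phase at collection thus stays open on weak evidence, in the second form of the test tried, since the fall that prompted the first form carried it. Collection times are not given in the sources used here, and the transgene as the only cause was argued against by the low levels in groups without it, while DSS and the transgene acting together stay open as untested.

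On average over both treatments 12 genes differed between transgenic and wild-type mice, with Nxpe5 at 3.79, Hsd17b13 at 1.24 and Nnt at -1.09. Some of them differed little under DSS. Per2, Cox18, Afm and Kcnf1 were at 0.0671, 0.225, 0.261 and -0.27 with DSS, against -1.12, 0.778, 0.708 and -0.741 without. Milder colitis in transgenic mice as the only cause for the set was weakly argued against, since 83.3% of these genes differed by at least 0.5 times as much in the same direction without DSS. For DSS in wild-type mice 33.3% of them were called, against 1022 of all 19908 genes, so this share does not argue against it. Ephb3 differed by 0.128 without and 0.694 with DSS. Untreated mice had a part in picking these genes, which favours the first share. For the 12 genes as a set, DNA linked to the transgene or from another substrain cannot be told apart from an effect of the transgene, since 1 pair, Afm and Cox18, lay within 50 genes of each other and random sets reached 1 pair at their 95th percentile. Nnt was as low in the 15 axenic mice (mean 7.212, 6.68 to 7.67) as in transgenic mice (7.363). The labels do not call the axenic mice transgenic and place them in the same strain. Every conventional wild-type mouse read 7.90 or more, so the low level of Nnt did not need the transgene, and the cause was not tested. Axenic means of Camk2b (7.908), Per2 (7.674), Kcnf1 (5.838) and Cox18 (9.08) also lay nearer to the transgenic than to the wild-type mean. The rest of the 12 genes lay nearer to the wild-type mean.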

How the results depend on the processing

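Settings with within-array SD, pancreas, Xist or posterior Hox levels and those without low-spread arrays were chosen after seeing the data, and the others before. The cause was not tested where a count moved, unless stated. Counts are given in the order DSS in wild-type, DSS in transgenic, interaction, genotype without DSS, genotype with DSS, donor, wild-type flora and transgenic flora, where the main counts were 1022, 905, 31, 15, 1, 0, 13401 and 67. Array weights gave 5843, 3266, 232, 58, 339, 4886 and, for transgenic flora, 6655. All 35 arrays in 1 model gave 1870 and 600 for DSS, 23 and 36 for genotype, 1927 for donor and 661 for transgenic flora. Quantile normalization within each comparison gave 1804 for DSS in wild-type mice, 3 for genotype with DSS, 6637 for wild-type flora and 152 for transgenic flora. The higher share with it was 57.9% for transgenic flora against 97.0%, 61.8% for DSS in transgenic mice against 76.1% and 78.8% for the interaction against 96.8%. The smooth muscle covariate gave 506 and 47 for DSS, 16 for the interaction, 8 for genotype without DSS and 7113 for transgenic flora. All probe sets gave 18 for the interaction and 32 and 18 for genotype, and genes above the 40th percentile gave 8101 for wild-type flora, with fewer genes tested. The within-array SD covariate gave 3573, 350, 131, 24 and 69 for the first 5 comparisons and 1 for wild-type flora. Without the 7 low-spread arrays DSS in transgenic mice gave 587, genotype with DSS 11 and wild-type flora 5159. For DSS in transgenic mice this dropped only untreated TG31, and for genotype with DSS only WT55, so these repeat the leave-one-out fits. For wild-type flora it dropped controls CT677, CT517 and CT465. The pancreas covariate gave 451, 223, 20, 6 and 16 for the first 5 comparisons, 1444 for wild-type flora and 135 for transgenic flora. Posterior Hox as covariate gave 9 for DSS in wild-type mice, 0 for the interaction and 4 for genotype without DSS, and Xist gave 2 for genotype with DSS. Leaving out each mouse in turn, counts ranged from 424 to 1277, 178 to 1668, 4 to 59, 4 to 20, 1 to 11, 0 to 4700, 11735 to 13465 and 27 to 5307.

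With wild-type flora the spread covariate raised the median SE from 0.117 to 0.246 and lowered the median size of the change of called genes from 0.519 to 0.158, so both a smaller change and a larger error ended the calls. Rises of at least 2-fold went from a median of 1.21 to 0.519. Lists passed by camera in the same order went with an estimated correlation to 5, 0, 2, 1, 1, 0, 0 and 1. With fry they went to 15, 9, 3, 1, 2 and 1 in the first 6 comparisons and to 3 with transgenic flora. Camera with the SD covariate passed 12 for the interaction, 10 for genotype without DSS, 13 for wild-type and 16 for transgenic flora, and without low-spread arrays 13 for the interaction and 14 for genotype with DSS. List scores past adjustment over 39 lists were 20 for DSS in wild-type and 13 in transgenic mice, 19 for wild-type flora and 0 in the other 4 comparisons of 2 groups, with 2, 8, 14 and 14 at an unadjusted exact p under 0.05. With a median over genes they went to 13 for DSS in wild-type mice. With each mouse left out in turn they ranged from 0 to 23 and 0 to 19 for DSS, 0 to 0 for both genotype comparisons and the donor comparison, 10 to 20 for wild-type flora and 0 to 9 for transgenic flora. The inflammation score for DSS in transgenic mice was 0.186 as a median (exact permutation p = 0.0794) and 0.291 with scaled genes (exact permutation p = 0.135), no longer past 0.05. That for transgenic flora was 0.475 with scaled genes (exact permutation p = 0.0794), and that for wild-type flora was 1.07 with genes above the 40th percentile (exact permutation p = 0.0397). Leave-one-out scores ranged from 0.675 to 1.0 and 0.165 to 0.448 for DSS, -0.0118 to 0.0367 and -0.69 to -0.292 for genotype, -0.0285 to 0.317 for donor, 0.405 to 0.75 for wild-type and 0.632 to 0.88 for transgenic flora. The leave-one-out correlation of the DSS responses ranged from 0.536 to 0.757 and that of genotype and donor effects from -0.456 to 0.171.

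Without the 7 low-spread arrays camera turned for genotype with DSS in goblet cell (adjusted p = 0.875), respiratory chain (0.000296) and pancreas genes (0.45), and for transgenic flora in cell-cycle genes (0.00592). With the SD covariate it turned for donor in oxidant defence (adjusted p = 0.46), endoplasmic reticulum stress (0.724), hypoxia (0.435), fibroblast (0.00433), squamous (0.797) and anterior Hox genes (0.0102). For wild-type flora it turned in eosinophil (adjusted p = 0.238), cell-cycle (0.0024), smooth muscle (6.48e-07), squamous (0.591) and anterior Hox genes (0.336), and for transgenic flora in cell-cycle (3.9e-07), respiratory chain (0.424) and squamous genes (0.581). In wild-type flora Ifnz turned to 0.0786, Usp17ld to 0.0247 and Gpr31b to 0.36 with the SD covariate, and Reg1 to -0.0447 with the pancreas covariate. With the posterior Hox covariate Hoxd11 turned to 0.30 and Hoxd13 to 0.21 for DSS in wild-type mice, where both genes are part of the covariate. Of 9105 values of named genes under the alternatives, 8204 stayed on the same side of the threshold, 689 no longer passed and 206 newly passed. A further 6 turned direction while called in the main or the alternative setting. Turns of genes called in neither setting were counted among the 8204. Arrays have no read depth, and how far signal over background limited precision was not tested.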
